A study of Mus musculus with 12 samples.

How the data were processed

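The assay was RNA-seq of naive CD4 T cells of C57BL/6 mice, of which more than 95% carried the sorted phenotype per the labels' protocols. Per those protocols the cells were stimulated through CD3 and CD28 for 24 h with IL-6 at 20 ng/mL, IL-1β, IL-21 and IL-23 at 10 ng/mL each, TNFα and TGF-β1 at 5 ng/mL each, and antibodies to IFNγ and IL-4 at 10 µg/mL each, with or without 10 nM RA. Stranded libraries were sequenced as single reads of 100 bp. The deposited values are FPKM per gene, one table of 52635 genes and 12 libraries, made by the authors. The submitters' processing notes name Trimmomatic 0.32, STAR, HTSeq 0.6.1 and DESeq2, and the genome builds GRCm38.p5 and mm10, without saying which step each served. The annotation release and the strand setting of the counting are not given in the sources used here. No pooled or averaged columns were used, and no 2 libraries held identical values.

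Gene symbols and Ensembl identifiers were used as the deposited table gives them, after 2 symbols that a spreadsheet had turned into dates were restored. Positions and exon lengths came from GENCODE M21 on GRCm38, in which 52402 identifiers have an entry. In all, 26727 genes were at 0 in every library and 200 symbols belonged to more than 1 gene. Where whole reads are counted, FPKM times exon length takes steps of 1 read, and this step gave the depth by which each library was scaled, from 16289969 to 25534588 reads. Recovered reads summed to 1.06 to 1.07 times this depth in each library, and the cause was not tested. With up to 20 reads, 95.3 to 95.9% of values lay within 0.02 of a whole number of reads. Depth was read from the values and is not a count that the authors stated, and reads are not independent molecules, so it limits counting error only. Mitochondrial genes made up 3.12 to 4.26% of the FPKM total and transcripts like ribosomal RNA 0.351 to 1.73%. Some mitochondrially encoded genes were listed at 0 throughout, so a 0 is not read as absence, and no mean or ratio of FPKM is given for a group listed at 0.

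Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on log2(FPKM + 1), for the 11922 genes with an FPKM of at least 1 in at least 2 libraries. The model held 1 mean for each of the 6 groups of 2 libraries, so that all groups shared 1 estimate of the spread, with 6 residual degrees of freedom and 2.51 prior degrees of freedom. There were 9 comparisons: RA against no RA within each genotype, KO and TG against WT at each dose, and the difference of the RA effect between KO or TG and WT. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05, and a gene past it is said to have been called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and fitted differences of genes listed at 0 in a group depend on the pseudocount. Values are given as mean ± SD of FPKM and as log2 fold change ± SE.

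The design, the 32 gene lists, the rule for the genes named and the main alternatives were fixed before the data were examined. Lists with at least 3 tested members, 29 in all, were tested with camera in limma at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Calls of list members are also given adjusted over the list alone. The genes named were the 8 largest rises and 8 largest falls of each comparison among called genes whose groups did not overlap and whose mean FPKM was at least 2 in a group, leaving out predicted genes and receptor segments. To these were added up to 4 members of each described list with the smallest p, 20 fixed genes, and the highest members of lists of other cells' markers. Some genes that the rule names are not reported here. Genes listed beside their neighbours in runs on a chromosome, and those whose values at 0 are given, were partly chosen after their values were seen. Overlaps of calls are set beside n1 × n2 / N, and differences from the shared WT libraries beside 100 simulations of unchanged groups.

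Alternatives were a pseudocount of 0.1, no filter on low values, upper-quartile scaling, only the libraries compared in the fit, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were limma voom on reads recovered from FPKM and exon length (11905 genes), a sex term, leaving out X- and Y-linked genes, and leaving out each library for the genes called in WT. The code was tested on simulated reads for RA in WT with 11905 genes and an overdispersion of 0.02. It recovered 2 of 67 genes changed 1.5-fold, 25 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 6 of 11705 unchanged genes called, and 0 genes were called over the 9 comparisons when nothing had been changed. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.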

Results

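RNA was sequenced from 12 libraries of naive CD4 T cells of C57BL/6 mice, an inbred laboratory strain. The cells had been activated through CD3 and CD28 for 24 h in charcoal-stripped serum, from which most retinoids are removed, with cytokines that drive naive cells towards the interleukin-17-producing Th17 state. They received either no retinoic acid (RA) or 10 nM RA, the active derivative of vitamin A, which acts through nuclear receptors such as RARα, the product of Rara. The labels name 3 genotypes, wild type (WT), RARα KO and RARα TG, and each genotype had 2 libraries without RA and 2 with RA. The allele behind the KO label and the construct behind the TG label are not given in the sources used here. The depth by which the values were scaled was read from the step that 1 read makes in low genes. It was 22567762 and 17713512 reads in replicates 1 and 2 of WT without RA and 16969623 and 16289969 reads in WT with RA. The libraries labelled KO had 17303975 and 18526840 reads without RA and 18047694 and 17798230 with RA. Those labelled TG had 19734846 and 25534588 reads without RA and 16798996 and 25415030 with RA. Replicates correlated at 0.981 to 0.987 over genes on the log2 scale, and genes are not independent replicates. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries. In TG the replicates differed in sex and so came from different animals. In WT and KO this is not known. There, transcripts of antigen-presenting cells differed by replicate number in the same way at both doses, as given below, which points to separate preparations of cells.

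The first principal component held 40.3% of the variance and separated the libraries with RA from those without in every genotype, with the TG libraries at both ends, and the second, with 18%, separated the KO libraries from the TG libraries. Xist and Y-linked transcripts placed all 4 WT libraries as male, all 4 KO libraries as female, and in TG replicate 1 as male and replicate 2 as female at both doses. Transcripts of antigen-presenting cells differed between replicate numbers. Cd74, the class II invariant chain, stood at 12.7 and 82.7 FPKM in replicates 1 and 2 of WT without RA, and 12.4 and 84.7 in WT with RA. It stood at 13.5 and 37.9 in KO without RA, 12.8 and 40.5 in KO with RA, 15.7 and 26.2 in TG without RA and 16.0 and 21.8 in TG with RA. In all 6 groups 8 of 10 tested B-cell markers and 5 of 5 dendritic or class II markers were higher in replicate 2. These differences entered the spread between replicates. Markers of other cells also differed between groups: the mean FPKM of the 10 B-cell markers was 3.25 and 3.62 in TG without RA and 11.2 and 11.1 in TG with RA, a difference carried mostly by Ighm. Several mitochondrially encoded genes that all cells transcribe, such as mt-Co2 and mt-Co3, were listed at 0 in all 12 libraries, so a gene at 0 is described only as listed at 0.

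The gene named in the genotype labels was examined first. Rara (ENSMUSG00000037992, chromosome 11, 98927818 to 98974942 on GRCm38) stood at 16.5 and 18.9 FPKM in WT without RA and 12.3 and 14.2 in WT with RA. In the libraries labelled KO it stood at 19.5 and 19.3 without RA and 16.8 and 17.6 with RA, so the gene-level values were not lower than in WT. The KO minus WT difference was 0.13 ± 0.09 (log2 ± SE, adjusted p = 0.57) without RA and 0.36 ± 0.09 (adjusted p = 0.16) with RA, neither past the threshold. A value summed over the whole gene cannot show the deletion of part of it, and these libraries are therefore called the libraries labelled KO, with directions drawn against that label and not against a measured loss. In the libraries labelled TG, Rara stood at 72.8 and 63.3 FPKM without RA and 126 and 119 with RA. It was higher than in WT by 1.88 ± 0.09 without RA (adjusted p = 3.1e-05) and by 3.12 ± 0.09 with RA (adjusted p = 2.3e-06), with all TG libraries above all WT libraries. RA raised Rara within TG by 0.85 ± 0.09 (limma adjusted p = 0.00016). The gene-level value cannot tell transcripts of the construct behind the TG label from those of the gene itself. In WT the RA effect on Rara was -0.39 ± 0.09 (adjusted p = 0.031), a call that ended without WT 0 nM replicate 2 (-0.30) or without WT 10 nM replicate 1 (-0.29), and in the libraries labelled KO it was -0.16 ± 0.09 (adjusted p = 0.58).

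**Figure D1:**
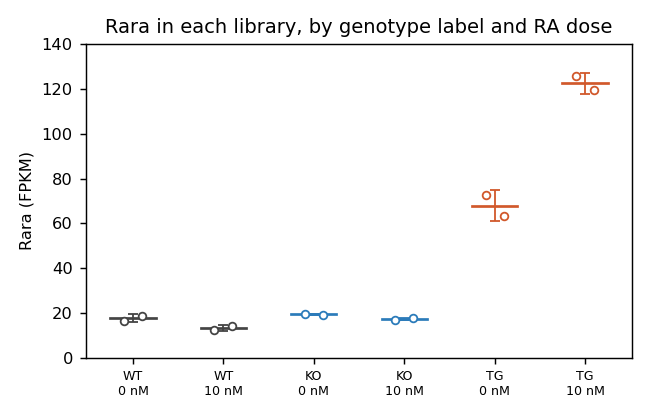
Rara in FPKM (vertical axis) in each library (circles), by genotype label and RA dose, with the mean (bar) and SD of the 2 libraries per group. The libraries labelled KO lie at 16.8 to 19.5 FPKM beside 12.3 to 18.9 in WT, and the libraries labelled TG lie at 63.3 to 126.

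The effect of RA in WT cells asks which genes the hormone controls under Th17-type stimulation. RA raised Hic1, a transcriptional repressor, from 0.408 ± 0.126 to 26.3 ± 2.62 FPKM (mean ± SD, n = 2 in every group), a log2 fold change of 4.28 ± 0.25 (± SE, limma adjusted p = 0.00016). Itga4, the α4 integrin of gut-homing lymphocytes, rose from 1.30 ± 0.108 to 37.0 ± 6.15 FPKM (4.04 ± 0.15, adjusted p = 1.5e-05). The cytokine gene Il9 fell from 261 ± 85.6 to 12.4 ± 4.32 FPKM (-4.29 ± 0.44, adjusted p = 0.0011), and Il17f, which encodes a cytokine made by Th17 cells, fell from 483 ± 101 to 115 ± 23.2 FPKM (-2.06 ± 0.22, adjusted p = 0.0012). Foxp3, the defining transcription factor of regulatory T cells, rose from 11.1 ± 1.64 to 53.7 ± 4.77 FPKM (2.18 ± 0.25, adjusted p = 0.0016). For every gene described as having risen or fallen, or as higher or lower, both libraries of one group lay above both libraries of the other. Of all tested genes 53.8% met this for RA in WT, 42.3% for RA in KO and 71.1% for RA in TG, so it is weak evidence alone. Hic1 (ENSMUSG00000043099, chromosome 11, 75164565 to 75169519), Itga4 (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123), Il9 (ENSMUSG00000021538, chromosome 13, 56479277 to 56482246), Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617) and Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) are placed on GRCm38.

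Of 11922 genes tested, 795 rose and 414 fell with RA in WT, 1209 in all, of which 87 rose and 46 fell by 2-fold or more. With upper-quartile scaling the calls divided into 667 rises and 554 falls. Beside Hic1 and Itga4, the largest rises included Gfi1, a transcriptional repressor (2.38 to 40.6 FPKM, 3.63 ± 0.19), the retinol transporter gene Stra6 (3.55 ± 0.35) and the nuclear receptor corepressor gene Nrip1 (3.83 to 33.6, 2.84 ± 0.12). Others were Crabp2, which carries RA to its receptors (4.24 to 34.1, 2.76 ± 0.24), Plac8 (2.51 ± 0.24) and the chemokine gene Xcl1 (2.31 ± 0.33). Beside Il9 and Il17f, the largest falls included Vim, which encodes vimentin (84.0 to 12.4 FPKM, -2.68 ± 0.31), the cytokine genes Il24 (-2.37 ± 0.32) and Il10 (-2.28 ± 0.24), and the costimulatory receptor gene Icos (57.7 to 15.4, -1.85 ± 0.14). Ly6c1 also lay among them (-2.02 ± 0.23), with the reservation that reads of near-identical Ly6 paralogs may be divided among them. The count depended on single libraries: 554 genes passed without WT 0 nM replicate 1, 342 without WT 0 nM replicate 2 and 477 without WT 10 nM replicate 1, where the lone library is assumed to vary like the other groups. With only the 4 WT libraries in the fit, 142 genes passed, and with the replicate number as a block 1689 did.

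Gene lists had been fixed before the data were examined. Of 15 tested genes that RA is known to induce, 9 rose, 1 fell and 5 did not pass, with 10 and 1 adjusted over the list alone (median log2 fold change 1.23, camera adjusted p = 4.2e-07, adjusted p = 0.090 with an estimated correlation). Tgm2, which encodes a transglutaminase, rose from 9.38 ± 0.890 to 49.6 ± 9.16 FPKM (2.28 ± 0.15), the gut-homing chemokine receptor gene Ccr9 by 1.57 ± 0.17 and the retinaldehyde reductase gene Dhrs3 by 0.93 ± 0.15. The member that fell was the receptor gene Rarg (-0.59 ± 0.15), whose call ended without any 1 of the WT libraries (-0.57 and -0.61 without replicates 1 and 2 of 0 nM, -0.58 and -0.60 without those of 10 nM). Of 23 genes of the Th17 programme, 0 rose, 7 fell and 16 did not pass, with 1 and 9 adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 7.1e-06, adjusted p = 0.090 with an estimated correlation). The falls included the interleukin-1 receptor gene Il1r1 (-1.58 ± 0.15) and the transcription factor gene Irf4 (-0.38 ± 0.05). Il17a stood at 9.01 ± 1.44 FPKM without RA and 8.99 ± 2.33 with RA (adjusted p = 0.98), not past the threshold. Among 18 regulatory T-cell genes, 7 rose, 2 fell and 9 did not pass, with 9 and 3 adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 0.025, adjusted p = 0.44 with an estimated correlation). Nt5e, which encodes the adenosine-forming enzyme CD73, rose from 10.3 ± 0.837 to 48.0 ± 3.34 FPKM (2.12 ± 0.18) and Izumo1r from 23.5 ± 0.192 to 62.8 ± 5.32 (1.38 ± 0.15), whereas Entpd1 (-1.18 ± 0.11) and Il2ra (-0.63 ± 0.07) fell.

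Of 10 Th2-associated genes tested, 1 rose, 5 fell and 4 did not pass, with 1 and 5 adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 0.013, adjusted p = 0.19 with an estimated correlation). The falls included the transcription factor genes Crem (-0.82 ± 0.10) and Nfil3 (-0.85 ± 0.10). Of 38 tested components of T-cell receptor signalling, 11 rose, 0 fell and 27 did not pass, with 13 and 1 adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 0.0023, adjusted p = 0.83 with an estimated correlation). Themis (0.88 ± 0.08) and Ubash3b (0.82 ± 0.10) were among the rises. Of 22 ribosome biogenesis genes, 0 rose, 5 fell and 17 did not pass, with 0 and 12 adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 2.8e-08, adjusted p = 0.40 with an estimated correlation). Of 21 genes of the unfolded protein and integrated stress responses, 0 rose, 4 fell and 17 did not pass, with 0 and 5 adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 1.3e-05, adjusted p = 0.40 with an estimated correlation). Sdf2l1 (-0.48 ± 0.05) was among the falls. These were the 7 of 29 tested lists that passed camera, and 0 passed with estimated correlations. Other fixed genes that missed the threshold included Itgb7 (-0.25 ± 0.16), Gpr15 (-0.38 ± 0.17) and Il22 (-1.85 ± 0.50, adjusted p = 0.054, a gene that passed with a pseudocount of 0.1, with upper-quartile scaling, with the replicate number as a block and without WT 0 nM replicate 1, at -2.59). So did Tbx21 (0.88 ± 0.29, adjusted p = 0.093, past it with the block), Gata3 (0.31 ± 0.13), Il2 (-0.04 ± 0.07) and Ifng (0.01 ± 0.36).

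**Figure D2:**
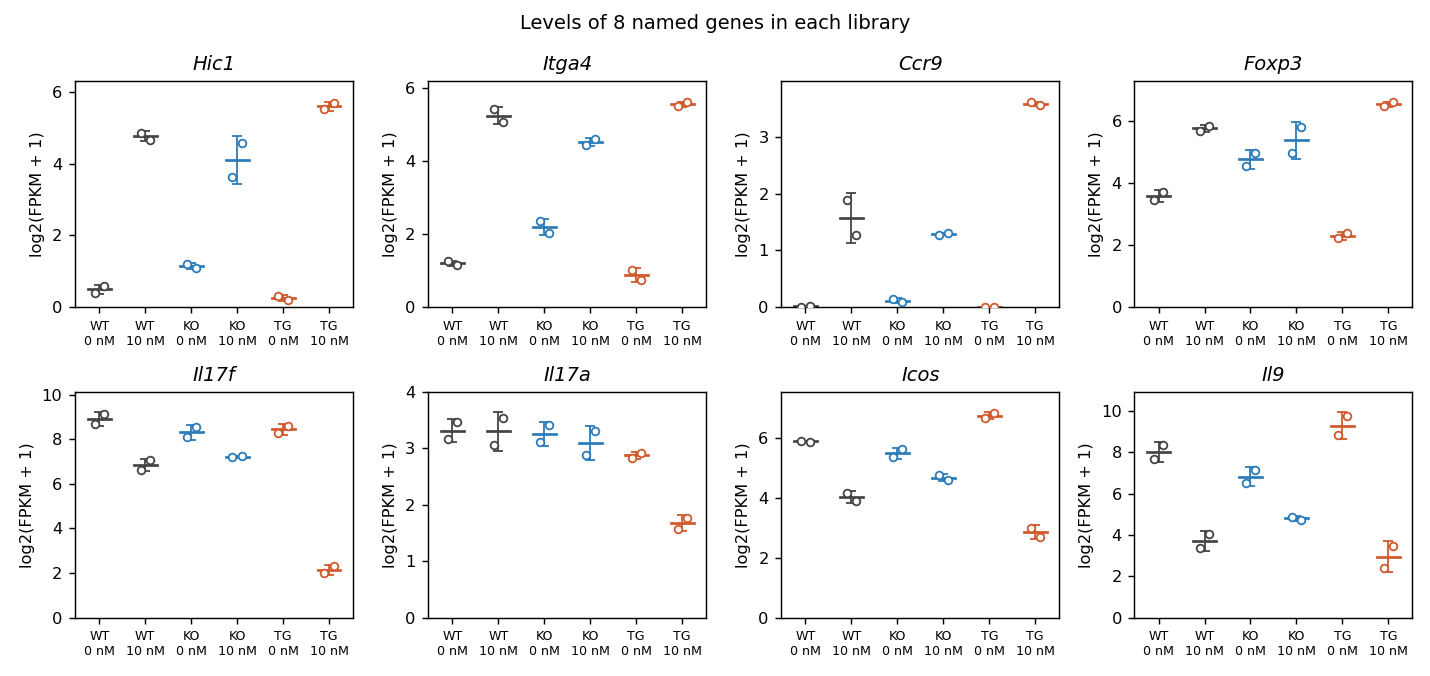
Levels of 8 genes as log2(FPKM + 1) (vertical axes) in each library (circles), by genotype label and RA dose, with the mean (bar) and SD of the 2 libraries per group. Hic1, Itga4, Ccr9 and Foxp3 have their highest and Il17f, Il17a, Icos and Il9 their lowest means in the TG libraries with RA.

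The same contrast in the libraries labelled KO asks how much of the RA response appears under that label. RA raised Hic1 from 1.22 ± 0.122 to 17.1 ± 8.08 FPKM (2.95 ± 0.25, limma adjusted p = 0.0035, n = 2 per group). It also raised Itga4 from 3.59 ± 0.715 to 21.9 ± 1.70 (2.33 ± 0.15, adjusted p = 0.00075) and Nrip1 from 4.24 ± 0.0221 to 17.3 ± 3.70 (1.79 ± 0.12, adjusted p = 0.0011). These 3 were the members of the RA-induced list that passed over all genes. Of 15 tested, 3 rose, 0 fell and 12 did not pass, with 8 and 1 adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 5.4e-08, adjusted p = 0.075 with an estimated correlation). The Th17 list had 0 calls over all genes among 23 tested and 5 falls adjusted over the list alone (median log2 fold change -0.16, camera adjusted p = 3.3e-05, adjusted p = 0.075 with an estimated correlation). Il17f stood at 319.7 ± 71.0 FPKM without RA and 148 ± 2.22 with RA (-1.08 ± 0.22, adjusted p = 0.12), Il9 at 114 ± 35.7 and 26.9 ± 2.02 (adjusted p = 0.14) and Foxp3 at 26.6 ± 5.64 and 42.9 ± 17.6 (adjusted p = 0.42). Ccr9 (1.18 ± 0.17, adjusted p = 0.058) and Nt5e (1.17 ± 0.18, adjusted p = 0.071) also missed the threshold. With the replicate number as a block 73 genes passed, Il17f, Il9 and Ccr9 among them, and Ccr9 also passed with a pseudocount of 0.1 and with voom on recovered reads. Ribosome biogenesis genes had 0 calls among 22 (median log2 fold change -0.09, camera adjusted p = 2.8e-05, adjusted p = 0.66 with an estimated correlation). Th2-associated genes had 0 among 10, while 1 rose and 5 fell adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 0.012, adjusted p = 0.18 with an estimated correlation). In all, 16 genes rose and 1 fell, with 1280 genes at an unadjusted p under 0.05. Without KO 0 nM replicate 2, 9 genes passed, without KO 10 nM replicate 1, 8 did, and without KO 10 nM replicate 2, 6. With only the 4 KO-labelled libraries in the fit 0 genes passed in limma, against 20 with all libraries and voom on recovered reads. Of the 29 lists 9 passed camera and 0 with estimated correlations.

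In the libraries labelled TG, which held more Rara, RA changed 4662 genes, of which 2350 rose and 2312 fell, and 526 rose and 228 fell by 2-fold or more. Izumo1r, a folate receptor family gene expressed on regulatory T cells, rose from 1.91 ± 0.508 FPKM to 127 in each library with RA (5.47 ± 0.15, limma adjusted p = 1.6e-07, n = 2 per group). Mdk, which encodes the growth factor midkine, rose from 1.06 ± 0.0737 to 74.5 ± 10.9 FPKM (5.19 ± 0.12), and Foxp3 from 3.97 ± 0.447 to 93.3 ± 5.51 (4.25 ± 0.25, adjusted p = 4.9e-06). Il17f fell from 348 ± 58.1 to 3.47 ± 0.704 FPKM (-6.29 ± 0.22, adjusted p = 4.9e-07) and Il9 from 648 ± 284 to 7.19 ± 4.05 (-6.33 ± 0.44, adjusted p = 1.4e-05). Further large rises were those of Hic1 (5.36 ± 0.25), Gfi1 (0.786 to 70.5 FPKM, 5.34 ± 0.19), Stra6 (5.12 ± 0.35), Crabp2 (3.98 to 169.6, 5.08 ± 0.24), the interferon regulatory factor gene Irf8 (4.72 to 165, 4.86 ± 0.19) and Itga4 (0.845 to 45.6, 4.66 ± 0.15). Further large falls were those of Vim (264 to 3.63 FPKM, -5.82 ± 0.31), Icos (105 to 6.21, -3.89 ± 0.14), Il22 (17.2 to 0.347, -3.66 ± 0.50) and Il24 (-3.35 ± 0.32). Ccr9 was listed at 0 in both TG libraries without RA and stood at 11.3 and 10.9 FPKM with RA.

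By list, 12 of 15 RA-induced genes rose and 1 fell, and the same numbers held adjusted over the list alone (median log2 fold change 3.0, camera adjusted p = 1.2e-08, adjusted p = 0.069 with an estimated correlation). Of 23 Th17 genes, 3 rose, 17 fell and 3 did not pass, with 3 and 18 adjusted over the list alone (median log2 fold change -0.74, camera adjusted p = 2.1e-05, adjusted p = 0.069 with an estimated correlation). Il17a fell from 6.37 ± 0.314 to 2.20 ± 0.309 FPKM (-1.21 ± 0.20), and Ahr, which encodes the aryl hydrocarbon receptor, fell as well (-1.27 ± 0.09). Regulatory T-cell genes gave 10 rises and 4 falls among 18 (10 and 6 adjusted over the list alone, median log2 fold change 0.55, camera adjusted p = 0.048, adjusted p = 0.69 with an estimated correlation). Nrp1 rose (2.50 ± 0.13) and Entpd1 fell (-1.78 ± 0.11). In the TGF-β response list 13 of 18 rose and 2 fell (13 and 3 adjusted over the list alone, median log2 fold change 0.62, camera adjusted p = 0.00015, adjusted p = 0.16 with an estimated correlation). The rises included the receptor gene Tgfbr2 (1.84 ± 0.13) and Pmepa1 (1.04 ± 0.05). All but 1 of 22 ribosome biogenesis genes, 21, fell (22 adjusted over the list alone, median log2 fold change -0.43, camera adjusted p = 1.2e-08, adjusted p = 0.32 with an estimated correlation), for example Rrp12 (-0.72 ± 0.08). Th2-associated genes gave 2 rises and 6 falls among 10, also adjusted over the list alone (median log2 fold change -1.13, camera adjusted p = 0.020, adjusted p = 0.18 with an estimated correlation). Crem (-2.10 ± 0.10) and Nfil3 (-2.0 ± 0.10) were among the falls. Genes outside these programmes also moved: Tbx21, the Th1 regulator, rose from 1.48 ± 0.0205 to 15.8 ± 1.68 FPKM (2.76 ± 0.29), and Gata3 by 0.60 ± 0.13. Some markers of other lymphocytes differed with RA here too, with Nkg7 at 1.02 ± 0.430 FPKM without RA and 32.7 ± 1.34 with RA (4.07 ± 0.37) and Klrd1 at 47.2 ± 3.98 and 4.76 ± 0.691 (-3.07 ± 0.34). The immunoglobulin gene Ighm, the highest of the B-cell markers, stood at 27.5 and 27.6 FPKM without RA and 101 and 95.9 with RA (1.80 ± 0.48), a call that ended without any 1 of the TG libraries (1.80 without either replicate of 0 nM, 1.76 and 1.84 without replicates 1 and 2 of 10 nM). Of the 29 lists 12 passed camera and 0 did with estimated correlations.

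Whether the RA effect itself differed from WT was tested gene by gene. In the libraries labelled KO the difference passed in limma for 1 gene, the pseudogene Rbpsuh-ps1, with 640 genes at an unadjusted p under 0.05. With no difference at all, a share of 0.05 of the 11922 tested genes would lie there, and 640 is near that share. Rbpsuh-ps1 (ENSMUSG00000081770, chromosome 4, 49350522 to 49351527 on GRCm38) was listed at 0 in both KO-labelled libraries without RA and stood at 4.96 and 4.30 FPKM with RA. It stood at 0.0440 and 0 FPKM in WT without RA and at 0 in both WT libraries with RA, and as a pseudogene it may take reads of a related gene. Its difference, 2.52 ± 0.17 (adjusted p = 0.0028), depends on the pseudocount: it was 5.82 ± 0.91 with a pseudocount of 0.1 and 7.95 ± 1.16 with voom on recovered reads, where its larger error ended the call and 0 genes passed. With no filter on low values 21 genes passed. Without KO 10 nM replicate 1, 2 genes passed, and without KO 10 nM replicate 2, 4. Several RA-induced genes had smaller effects under the KO label without passing, as for Itga4 (-1.71 ± 0.21, adjusted p = 0.096) and Tgm2 (-1.41 ± 0.22, adjusted p = 0.18). Of the 15 genes of that list, 5 had a smaller effect adjusted over the list alone and 0 over all genes (median difference -0.56, camera adjusted p = 9.9e-08, adjusted p = 0.13 with an estimated correlation). The Th17 list had 0 calls over all genes (median difference 0.13, camera adjusted p = 0.00045, adjusted p = 0.15 with an estimated correlation). Over the 1209 genes called in WT, the RA effect signed by the WT direction had a median of 0.21 under the KO label against 0.45 in WT, and 98.4% kept the WT sign. That median was 0.32 without WT 0 nM replicate 2.

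In the libraries labelled TG the RA effect differed from that in WT for 892 genes, 566 with a higher and 326 with a lower effect. Each difference given here separated every treated-minus-untreated difference of one genotype from all of the other. Izumo1r differed by 4.09 ± 0.21 (adjusted p = 3.7e-05), Mdk by 3.88 ± 0.17 (adjusted p = 2.2e-05) and Irf8 by 3.42 ± 0.27, all larger in TG. Il17f differed by -4.23 ± 0.31 (adjusted p = 0.00016), Vim by -3.15 ± 0.43 and Icos by -2.04 ± 0.20, all with a deeper fall in TG. Foxp3 differed by 2.07 ± 0.35. Of the 15 RA-induced genes, 8 had a larger effect in TG, or 14 adjusted over the list alone (median difference 1.24, camera adjusted p = 4.9e-10, adjusted p = 0.071 with an estimated correlation). Crabp2 (2.33 ± 0.34) and Asb2 (1.78 ± 0.23) were among them. Of 18 TGF-β response genes, 9 had a higher effect, or 11 with 2 lower adjusted over the list alone (median difference 0.44, camera adjusted p = 3.2e-06, adjusted p = 0.10 with an estimated correlation). Pmepa1 (0.65 ± 0.08) was an example. Of 23 Th17 genes, 1 had a higher and 7 a lower effect, or 1 and 9 adjusted over the list alone (median difference -0.48, camera adjusted p = 0.00060, adjusted p = 0.11 with an estimated correlation). The count fell to 508 without WT 0 nM replicate 1, 469 without WT 0 nM replicate 2, 574 without WT 10 nM replicate 2, 499 without TG 0 nM replicate 2, 485 without TG 10 nM replicate 1 and 512 without TG 10 nM replicate 2, and it was 1248 with the replicate number as a block. Over the 1209 genes called in WT the signed RA effect in TG had a median of 0.72 and 98.3% kept the WT sign. The median was 1.36 without WT 0 nM replicate 2 and 1.09 without WT 10 nM replicate 1, sets that hold fewer genes called in WT. Calls in WT and TG shared 712 rises and 385 falls, where independent lists would share 156.7 and 80.3, and 5 genes moved in opposite directions.

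**Figure D3:**
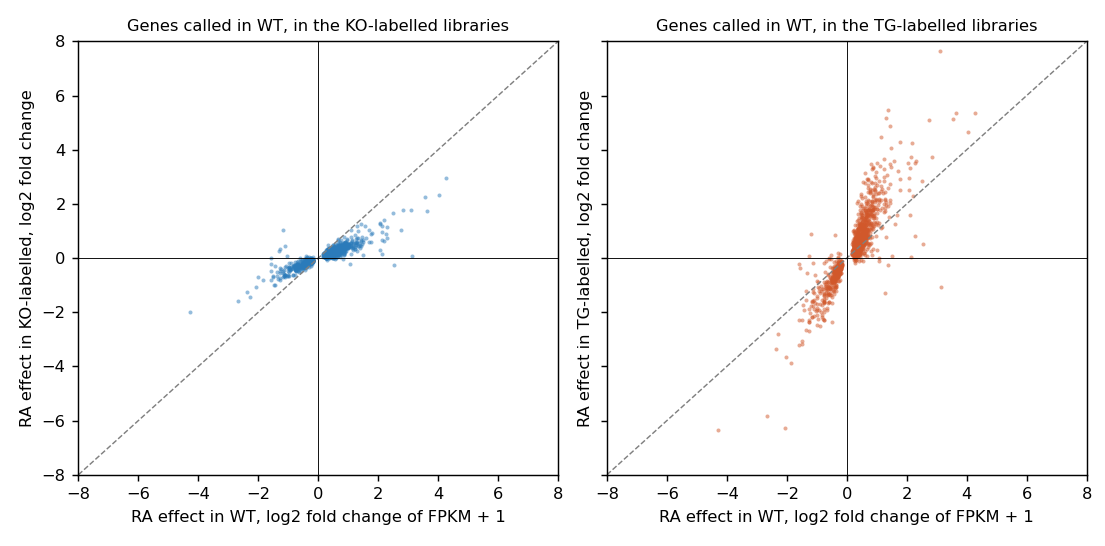
RA effect (log2 fold change of FPKM + 1) in the libraries labelled KO (left, vertical axis) and TG (right, vertical axis) against that in WT (horizontal axes) for the 1209 genes called in WT, 1 point per gene, with the line of equal effects dashed. Signed by the WT direction, the median effect is 0.45 in WT, 0.21 under the KO label and 0.72 in TG.

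The libraries labelled KO were next set against WT at each dose, which asks what the label changes apart from the response to RA. Without RA, 138 genes were higher and 69 lower than in WT. H60b, which encodes a ligand of the NKG2D receptor, stood at 0.915 ± 0.307 FPKM in WT and 24.0 ± 1.06 under the KO label (3.71 ± 0.16, limma adjusted p = 1.8e-05, n = 2 per group). Inppl1, which encodes an inositol phosphatase, was higher by 1.96 ± 0.10, and Lgals3, which encodes galectin-3, by 1.89 ± 0.20, a call that ended with sex as a term (1.86). The ribosomal protein gene Rpl29 was lower, at 2.02 ± 0.674 against 23.6 ± 1.44 FPKM (-3.05 ± 0.18, adjusted p = 0.00014), as was Nt5e, at 0.924 ± 0.451 against 10.3 ± 0.837 (-2.57 ± 0.18, adjusted p = 0.00037). Xkr6 (-2.07 ± 0.14), Pxylp1 (-1.28 ± 0.09) and Maged1 (-1.14 ± 0.09) were also lower. Ccnb1ip1 (ENSMUSG00000071470, chromosome 14, 50789248 to 50807732 on GRCm38) stood at 14.5 and 19.7 FPKM in WT without RA and 13.1 and 17.2 with RA and was listed at 0 in all 8 KO and TG libraries. Elobl (ENSMUSG00000057534, chromosome 11, 88964658 to 88966931) stood at 5.2 and 3.95 FPKM under the KO label without RA and 6.32 and 4.38 with RA and was listed at 0 in all 8 other libraries. H60b, Rpl29, Xkr6 and Elobl have paralogs, pseudogene copies or overlapping neighbours, and the strand setting of the counting is not given in the sources used here, so their values are uncertain. H60b (ENSMUSG00000075297, chromosome 10, 22158586 to 22288849), Rpl29 (ENSMUSG00000048758, chromosome 9, 106429454 to 106431568) and Nt5e (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092) are placed on the same build. Foxp3 stood at 11.1 ± 1.64 in WT and 26.6 ± 5.64 FPKM under the KO label (adjusted p = 0.062, not past the threshold, which it passed with voom and with the replicate number as a block).

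Among the lists, 25 sterol and lipid synthesis genes had 0 calls over all genes and 11 lower adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 6.9e-08, adjusted p = 0.40 with an estimated correlation). T-cell receptor signalling genes had 0 calls over all genes among 38 and 14 higher adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 4.8e-06, adjusted p = 0.50 with an estimated correlation). The γδ T-cell marker Tcrg-C2 stood at 1.79 ± 0.475 against 0.289 ± 0.203 FPKM (1.11 ± 0.21), a call that ended with sex as a term (1.05), with no filter on low values (1.11) and without WT 0 nM replicate 1 (0.95) or 2 (1.27) or KO 0 nM replicate 1 (1.29) or 2 (0.94). The RA-induced list had 1 call among 15, also adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.032, adjusted p = 0.40 with an estimated correlation). That gene, Itga4, was higher by 0.99 ± 0.15, a call that ended with sex as a term (1.07) and without WT 0 nM replicate 1 (1.04), WT 0 nM replicate 2 (0.94) or KO 0 nM replicate 1 (0.83). The Th17 list held 1 lower gene among 23 (3 adjusted over the list alone, median log2 fold change -0.08, camera adjusted p = 0.00080, adjusted p = 0.20 with an estimated correlation). Of the 29 lists 12 passed camera and 0 did with estimated correlations. The count of 207 called genes depended on the libraries and the model: 80 passed without WT 0 nM replicate 1, 31 without WT 0 nM replicate 2, 34 without KO 0 nM replicate 1 and 47 without KO 0 nM replicate 2. All WT libraries were male and all libraries labelled KO female, and with sex as a term 35 genes passed, while 26 did with only the 4 libraries compared in the fit and 479 with the replicate number as a block.

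With RA, 56 genes were higher and 49 lower under the KO label than in WT. H60b was higher by 4.11 ± 0.16 (limma adjusted p = 8.4e-06, n = 2 per group), Inppl1 by 2.17 ± 0.10 and Hddc3 by 1.29 ± 0.11. Nt5e, which RA raised in WT, stood at 3.31 ± 0.757 against 48.0 ± 3.34 FPKM in WT (-3.52 ± 0.18, adjusted p = 4.9e-05). Rpl29 (-3.23 ± 0.18), Xkr6 (-2.35 ± 0.14) and Art2b (0.571 against 8.69 FPKM, -2.58 ± 0.28) were lower, and the Art2b call ended with sex as a term (-2.21). Of 15 RA-induced genes, 0 were higher and 3 were lower, or 1 and 6 adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 0.00040, adjusted p = 0.30 with an estimated correlation). Those 3 were Nrip1 (-0.93 ± 0.12), Crabp2 (-1.47 ± 0.24) and Tgm2 (-1.0 ± 0.15), and with sex as a term none of the 3 passed (-0.89, -1.21 and -1.0). Nrip1 lost its call without WT 10 nM replicate 1 (-0.87) or replicate 2 (-0.99), Crabp2 without WT 10 nM replicate 1 (-1.37), replicate 2 (-1.57) or KO 10 nM replicate 1 (-1.12), and Tgm2 without WT 10 nM replicate 2 (-0.81) or KO 10 nM replicate 1 (-0.78). Crabp2 and Tgm2 also lost theirs with no filter on low values, and all 3 with only the 4 libraries compared in the fit. The retinoid pathway list had 0 higher and 2 lower among 16, or 2 and 5 adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.035, adjusted p = 0.34 with an estimated correlation). Sterol and lipid synthesis genes had 0 calls over all genes and 11 lower of 25 adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 3.2e-10, adjusted p = 0.34 with an estimated correlation). Of the 29 lists 13 passed camera and 0 did with estimated correlations. The count of 105 became 46 without WT 10 nM replicate 2 and 44 without KO 10 nM replicate 1, 28 with sex as a term, 14 with only the 4 libraries compared in the fit and 174 with the replicate number as a block.

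At both doses 71 genes were called between the KO label and WT, each in the same direction at both doses. They lay unevenly over the genome: 20 were on chromosome 7, where 5.30 would be there by the share of tested genes (two-sided Fisher's exact test, adjusted p = 2.9e-06), 12 on chromosome 9 (3.83, adjusted p = 0.0026) and 11 on chromosome 14 (2.98, adjusted p = 0.0017). Runs of such genes included Fanci, Ap3s2, Rccd1, Hddc3 and Hdgfl3 at 79.4 to 81.9 Mb on chromosome 7, 7 genes with Rpl29 at 104.0 to 107.3 Mb on chromosome 9, and 8 genes with Lgals3 and Ccnb1ip1 at 46.8 to 54.9 Mb on chromosome 14. A run joined at least 3 of the 71 genes whose neighbouring starts lay no more than 5 Mb apart, whatever other genes lay between them. Of genes named above, Nt5e lay in a run of 3 genes, all lower, at 85.3 to 90.1 Mb on chromosome 9. Inppl1 lay in a run of 9 at 97.4 to 104.5 Mb on chromosome 7, and Xkr6 in a run of 3, all lower, at 63.5 to 63.8 Mb on chromosome 14. Near Rara, a run of 4 genes (Rsad1, Tns4, Ifi35 and Rdm1) was spread over 94.5 to 101.6 Mb of chromosome 11. That chromosome held 10 of the 71 genes, against 5.91 by its share (Fisher's exact test, adjusted p = 0.25). Another run of 4 there, with Elobl and all higher, lay at 88.7 to 89.0 Mb. Chromosome 14 also held 24 of the genes called between TG and WT at both doses, where 8.89 would be there by its share (adjusted p = 0.00019), and of the 8 genes of its run 6 without RA and 5 with RA were called in the same direction in TG against the same WT libraries. These runs were looked at after the calls had been seen.

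**Figure D4:**
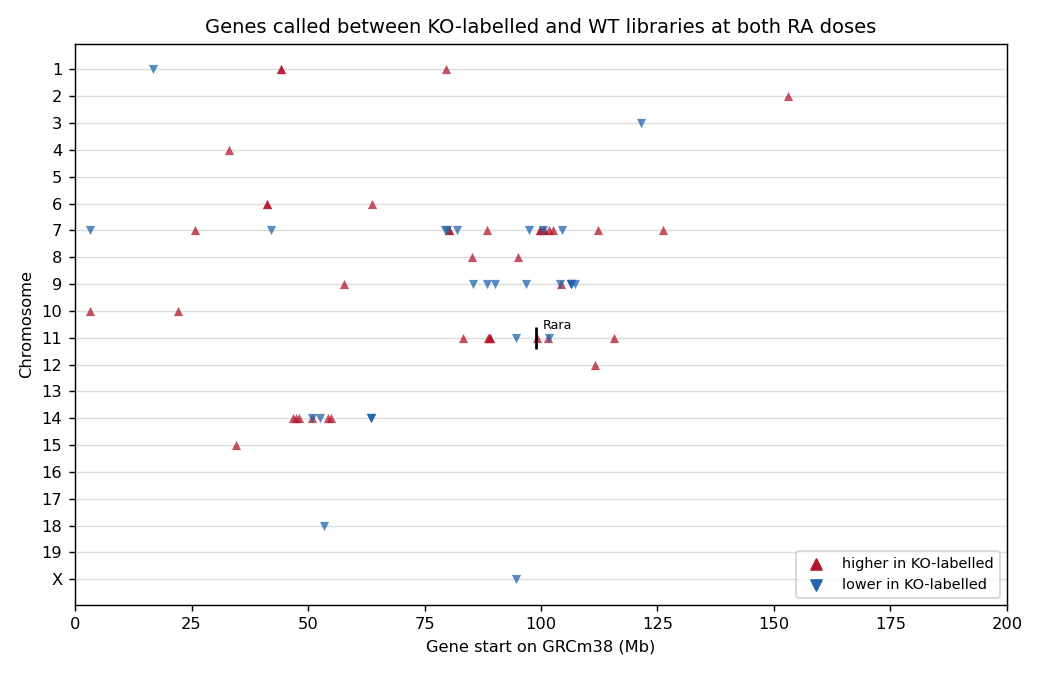
Start positions on GRCm38 in Mb (horizontal axis), by chromosome (vertical axis), of the 71 genes called between the libraries labelled KO and WT at both RA doses, with upward triangles for genes higher and downward triangles for genes lower under the KO label and Rara marked by a bar. Chromosome 7 holds 20 of them, chromosome 9 holds 12 and chromosome 14 holds 11.

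The libraries labelled TG were compared with WT in the same way. Without RA, 268 genes were higher and 246 lower. Beside Rara, Gcnt4, which encodes a glycosyltransferase, stood at 8.09 ± 1.08 against 0.303 ± 0.0519 FPKM (2.80 ± 0.12, limma adjusted p = 2.4e-05, n = 2 per group), and Lgals3 (1.88 ± 0.20) and the ubiquitin ligase gene Nedd4 (1.72 ± 0.16) were also higher. Izumo1r was lower, at 1.91 ± 0.508 against 23.5 ± 0.192 FPKM (-3.08 ± 0.15, adjusted p = 3.1e-05). Among the 8 largest falls were 4 GTPase genes of the Gimap cluster, led by Gimap4 at 4.96 ± 0.167 against 94.2 ± 1.34 FPKM (-4.00 ± 0.26), whose related sequences may share reads. Il2 (19.8 ± 0.532 against 46.7 ± 2.41 FPKM, -1.20 ± 0.07, adjusted p = 0.00011) and Irf8 (-1.84 ± 0.19) were lower, while the receptor genes Il12rb2 (1.40 ± 0.17) and Lag3 (1.21 ± 0.15) were higher. Foxp3 was lower (-1.28 ± 0.25), a call that ended with sex as a term (-1.36) and without WT 0 nM replicate 1 (-1.42), WT 0 nM replicate 2 (-1.14), TG 0 nM replicate 1 (-1.19) or TG 0 nM replicate 2 (-1.37). Of 38 T-cell receptor signalling genes, 0 were higher and 6 lower, or 1 and 7 adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 0.00015, adjusted p = 0.77 with an estimated correlation). The RA-induced list, which did not pass camera, had 1 lower gene among 15, Tgm2 (-1.25 ± 0.15), with 1 higher and 2 lower adjusted over the list alone. Of the 29 lists 5 passed camera and 0 did with estimated correlations. The γδ T-cell marker Trdc stood at 3.49 ± 0.102 against 7.35 ± 0.345 FPKM (-0.89 ± 0.11). The count of 514 became 161 without WT 0 nM replicate 1, 137 without WT 0 nM replicate 2, 224 without TG 0 nM replicate 1 and 131 without TG 0 nM replicate 2. With sex as a term 200 genes passed, 47 did with only the 4 libraries compared in the fit, and 823 did with the replicate number as a block.

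With RA, 816 genes were higher and 553 lower in TG than in WT. Mdk stood at 74.5 ± 10.9 against 5.07 ± 0.50 FPKM (3.63 ± 0.12, limma adjusted p = 2.4e-06, n = 2 per group). The linker histone gene H1fx stood at 15.9 ± 3.16 against 0.447 ± 0.153 (3.54 ± 0.26) and Trat1, which encodes an adaptor of the T-cell receptor, at 51.6 ± 17.2 against 5.64 ± 1.89 (2.97 ± 0.30). Il17f was lower, at 3.47 ± 0.704 against 115 ± 23.2 FPKM (-4.69 ± 0.22, adjusted p = 6.9e-06), as were Il17a (2.20 ± 0.309 against 8.99 ± 2.33, -1.63 ± 0.20) and Il2 (-0.89 ± 0.07). Akr1c18, which encodes a hydroxysteroid dehydrogenase, was lower (-3.89 ± 0.35). Of 15 RA-induced genes, 11 were higher and 0 lower, or 12 and 0 adjusted over the list alone (median log2 fold change 1.09, camera adjusted p = 2.6e-09, adjusted p = 0.082 with an estimated correlation). Crabp2 (2.27 ± 0.24), Ccr9 (2.02 ± 0.17), Dhrs3 (1.71 ± 0.15) and Asb2 (1.65 ± 0.16) were examples. Of 23 Th17 genes, 1 was higher and 9 lower, or 1 and 10 adjusted over the list alone (median log2 fold change -0.38, camera adjusted p = 5.0e-05, adjusted p = 0.082 with an estimated correlation). TGF-β response genes gave 8 higher and 0 lower among 18, or 8 and 1 adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 0.00013, adjusted p = 0.12 with an estimated correlation). Ltbp3 (1.46 ± 0.12) was higher. Of 22 ribosome biogenesis genes 9 were lower, or 17 adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 2.6e-08, adjusted p = 0.34 with an estimated correlation). Foxp3 stood at 93.3 ± 5.51 against 53.7 ± 4.77 FPKM (adjusted p = 0.083) and Itga4 differed by 0.30 ± 0.15 (adjusted p = 0.23), neither past the threshold, which Foxp3 passed with the replicate number as a block and with only the 4 libraries compared in the fit. The CD8-associated marker Crtam was higher by 0.90 ± 0.15, and Trdc was lower (-0.97 ± 0.11). Of the 29 lists 10 passed camera and 0 did with estimated correlations. The count of 1369 became 700 without WT 10 nM replicate 2, 632 without TG 10 nM replicate 1 and 626 without TG 10 nM replicate 2, 422 with only the 4 libraries compared in the fit and 1814 with the replicate number as a block.

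Both genotypes were compared with the same WT libraries, so their differences from WT share the chance values of those libraries. Over tested genes the KO and TG differences without RA had a covariance of 0.0128, against 0.0170 in 100 simulations of unchanged groups against shared controls, and a correlation of 0.152 against a simulated 0.501. With RA the covariance was 0.0165 against a simulated 0.0168 and the correlation 0.164 against 0.496. The simulated correlation follows from the shared controls alone, and effects of 1 genotype that the other lacks lower the measured value. The lower correlations therefore do not show that KO and TG were less alike than unchanged groups. With a pseudocount of 0.1 the covariances were 0.0725 without and 0.0777 with RA, where no simulation was run. Without RA 17 genes were higher in both genotypes and 12 lower in both, where independent lists would share 3.10 and 1.42, and 45 moved in opposite directions, where 4.40 would. With RA 10 genes were higher and 9 lower in both, against 3.83 and 2.27, and 20 moved in opposite directions, against 5.95. Lgals3 without RA (1.89 ± 0.20 under the KO label and 1.88 ± 0.20 in TG) and Xkr6 at both doses were among the genes shared. With 2 WT libraries per dose the controls could not be divided, and part of any excess of shared calls may come from them.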

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

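The tests of neighbouring genes, of the spread of the KO-labelled libraries and of sex in TG were chosen after the results they bear on had been seen, as were the alternatives with a sex term and the use of the planned upper-quartile scaling as a test, and the other tests of this part were set before.

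The 71 genes called between the KO label and WT at both RA doses, all with the same direction at both, often stood close together on the genome. Of them 43 had another of the set within 2 Mb, where 1000 draws of as many tested genes gave a median of 13 and at most 28. A candidate explanation is chromosome segments that differ between the mouse lines, such as those carried along from the strain of an altered allele. Of the 8 genes in the chromosome 14 run with Lgals3, 6 without RA and 5 with RA were called in the same direction in TG against the same WT libraries. That run was therefore not particular to the KO label. Sex, which follows the genotype in WT and KO, stays open. The female minus male difference of the TG libraries, signed by the KO direction, was taken over the 70 autosomal genes of the set. Its median was 0.00250 (95% range over resampled genes 0 to 0.0182), against a median KO minus WT size of 1.03. The shared spread held male and female TG libraries, so genes with a large sex difference were unlikely to be called. Without RA the Xist difference, 6.00, passed with only the 4 libraries compared in the fit and not in the reported fit. The small median thus follows largely from the choice of genes and cannot decide. With a sex term, at a median size of 1.02, the median SE rose from 0.115 to 0.168 and 21 of the set still passed. RARα status acting through RA-responsive genes stays open: 33.8% of the set was called in RA in TG, within the 26.8 to 47.9% of sets matched on expression, so this share cannot tell. Genotype itself, and anything else the mouse lines differ in, stays open too, and Rara was not lower under the KO label.

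The RA response was smaller under the KO label than in WT, by the median signed effect of the genes called in WT. The median within-group SD of the KO-labelled libraries was 0.960 of that of WT. Noisier libraries would widen the effects without lowering their median, so this ratio bears on counts of calls and not on the median. Sizes inflated by picking genes called in WT were argued against by the genes called in TG, whose libraries entered neither effect. Their median signed RA effect under the KO label was 0.513 of that in WT (95% range over resampled genes 0.495 to 0.531). Genes are not independent replicates, so this range does not cover the spread between libraries or animals. The smaller effect lay more in the untreated libraries. Over the 4662 genes called in TG the mean signed log2 level without RA was -0.0466 and -0.0686 under the KO label, against -0.150 and -0.168 in WT. With RA it was 0.0615 and 0.0708, against 0.116 and 0.0796. A weaker but not absent RA response, as the span between doses, is a hypothesis found and tested on the same data. The test of the difference itself passed for 1 gene in limma. At an unadjusted p under 0.05 lay 640 genes, near the share expected with no difference. With voom 0 passed, where the difference of that gene was larger (7.95 ± 1.16 against 2.52 ± 0.17) and its error too, and with no filter on low values 21 did. Differences of origin, sex and background between the libraries stay open and were not separated from the label, and the gene-level Rara value cannot show a partial deletion.

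The RA response was larger in the libraries labelled TG, with 892 genes past the test of the difference. Deeper sequencing of the TG replicate 2 libraries was argued against by thinning all libraries to the smallest sum of recovered reads, which left 855 calls, 804 of them among the 892. Library scaling was argued against by 886 calls with upper-quartile scaling. A sex term cancels from these RA effects, so the male and female TG pairs were compared over the 859 autosomal genes of the difference. The RA effect of the female minus that of the male pair, signed by the TG minus WT direction, had a median of 0.0326. Its 95% range over resampled genes was 0.0198 to 0.0413, against a median TG minus WT size of 0.725. Sex as the cause would put the male pair at the WT effect and this median at 2 times that size. The male pair itself differed from WT by a median of 0.712, signed the same way. Both values follow largely from the choice of genes, because a call needs a small spread between TG replicates, which differ in sex. They cannot decide about sex, with 1 pair of libraries per sex. With Rara RNA higher in TG at both doses, a biological hypothesis is that more receptor widened the response to a fixed dose, found and tested on the same data. Receptor protein was not measured. Other differences of the TG line, such as where its construct lies, were not tested.

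Single genes with an RA effect that differed between genotypes were as follows, each as TG minus WT on the log2 scale unless said otherwise. Under the KO label the pseudogene Rbpsuh-ps1 differed from WT by 2.52 and was the 1 gene past that test. Higher in TG were Izumo1r (4.09), Mdk (3.88), H1fx (3.59), Irf8 (3.42), Gimap3 (3.34), Hrh3 (3.04), Eya2 (2.81) and Gimap9 (2.66). Eya2 was listed at 0 in both TG libraries without RA and Hrh3 in both WT libraries without RA, so their differences depend on the pseudocount. Lower in TG were Il17f (-4.23), Vim (-3.15), Gcnt4 (-2.76), Klrd1 (-2.39), Timp1 (-2.28), Il7r (-2.21), Havcr1 (-2.18) and Icos (-2.04). The Klrd1 call ended without WT 0 nM replicate 1 (-2.28) or 2 (-2.49), WT 10 nM replicate 2 (-2.20), TG 0 nM replicate 1 (-2.47) or 2 (-2.30), and TG 10 nM replicate 1 (-2.26) or 2 (-2.51). The Il7r call ended without WT 0 nM replicate 1 (-2.28) or 2 (-2.14), WT 10 nM replicate 1 (-1.72), TG 0 nM replicate 1 (-2.07) or 2 (-2.34), or TG 10 nM replicate 2 (-1.75). The calls of Hrh3 and Gcnt4 ended with voom on recovered reads.

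Among the genes fixed in advance, higher effects in TG were seen for Rara (1.24), Cyp26b1 (1.57), Dhrs3 (1.84), Ccr9 (2.03), Foxp3 (2.07) and Tbx21 (1.88), and lower ones for Il17a (-1.19) and Il23r (-1.05). The Rara value may include transcripts of the construct. The calls of Cyp26b1, Dhrs3 and Ccr9 ended with voom, and those of Cyp26b1 and Dhrs3 also with a pseudocount of 0.1. Ccr9 was listed at 0 in both TG libraries without RA and Il23r in both with RA, so their differences depend on the pseudocount. The Il23r call ended without WT 0 nM replicate 1 (-1.04) or 2 (-1.07) or TG 0 nM replicate 1 (-0.92). Il17a lost its call without WT 0 nM replicate 1 (-1.04) or 2 (-1.34), WT 10 nM replicate 2 (-0.95), TG 0 nM replicate 1 (-1.23) or 2 (-1.15), and TG 10 nM replicate 1 (-1.09) or 2 (-1.29). Tbx21 lost it without WT 0 nM replicate 2 (1.67), WT 10 nM replicate 1 (1.57), TG 0 nM replicate 1 (1.87) or 2 (1.88), and TG 10 nM replicate 1 (1.77) or 2 (1.98).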

How the results depend on the processing

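The alternatives with voom, with a sex term, without X- and Y-linked genes and without each library for the genes called in WT were chosen after the results had been seen. Of 15255 alternative values for 1189 pairs of a named gene and a comparison, 14116 stayed on their side of the threshold, 963 fell short of it, 176 came to pass it and 0 reversed direction. Of the 5796 values without 1 library 580 fell short and 35 came to pass. Depth of 16289969 to 25534588 reads limits the calls of low genes. In the simulated data, with 2 libraries per group, most 1.5-fold and many 2-fold changes were missed. Their overdispersion was set at 0.02 and not fitted to these libraries, whose median within-group SDs on the log2 scale were 0.0597 to 0.0770. The 1209 genes called for RA in WT had a median log2 size of 0.446, and 133 of them reached 2-fold. The share missed in the simulation therefore need not hold here.

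With only the libraries compared in the fit, and so fewer degrees of freedom, the calls were 142 for RA in WT, 0 for RA in KO (17 with all libraries and 1280 at an unadjusted p under 0.05 in limma), 26 and 14 for KO against WT without and with RA, and 47 and 422 for TG against WT. With no filter on low values RA in KO had 30.0 calls, the KO minus WT difference of RA effects 21, and the covariance of KO and TG effects with RA was 0.0109; the cause was not tested. With a pseudocount of 0.1 the KO minus WT difference had 0 calls. In the reported limma fit it had 1, with 640 genes at an unadjusted p under 0.05, near the share expected with no difference. With that pseudocount 8 lists passed for TG against WT without RA. The covariances were then 0.0725 without and 0.0777 with RA, where low genes weigh more by construction. With voom on recovered reads the KO minus WT difference had 0 calls. With a sex term, which follows genotype, KO against WT had 35 calls without and 28 with RA, TG against WT without RA 200, and the KO minus WT difference 3. With an estimated inter-gene correlation 0 lists passed in each of the 9 comparisons.

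Leaving out 1 library in turn gave 342 to 850.0 calls for RA in WT, 6 to 16 for RA in KO and 3233 to 4083 for RA in TG. It gave 31 to 80.0 calls for KO against WT without RA and 44 to 94 with RA, 131 to 224 for TG against WT without RA and 626 to 1041 with RA. For the differences of RA effects it gave 1 to 4 (KO minus WT) and 469 to 716 (TG minus WT) calls. For the genes called in WT the median signed RA effect ranged from 0.191 to 0.316 under the KO label and from 0.689 to 1.36 in TG. Fewer libraries, with the lone library assumed to vary like the other groups, account for lower counts by construction.

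The labels give the groups the same replicate numbers, with 2 numbers only, and the reported fit did not assume pairing. Within a genotype the values point to the same source of cells per number at both doses. In TG replicate 1 was male and replicate 2 female at both. The mean of the dendritic and class II markers without and with RA was 4.70 and 5.16 FPKM in WT replicate 1 and 31.1 and 32.8 in replicate 2. A fit paired within each genotype was not run, so the RA comparisons leave this pairing out. Deviations of libraries with the same number correlated at 0.327 in WT, 0.32 in KO and 0.147 in TG, and between genotypes at 0.00350 to 0.206. With the replicate number as a block 73 genes passed for RA in KO, 479 and 174 for KO against WT without and with RA, 823 for TG against WT without RA, where 9 lists also passed. It was 1689 for RA in WT, 5215 for RA in TG, 1814 for TG against WT with RA, 1248 for the TG minus WT and 1 for the KO minus WT difference. Counts of calls under the other alternatives stayed within 1.5 times the reported count.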

Other observations

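Both tests of RA-responsive genes without RA were chosen after the values had been seen, and the gene lists had been fixed before.

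Metabolic lists were also examined for RA in the libraries labelled TG. Of 25 sterol and lipid synthesis genes, 11 rose and 1 fell, the same numbers adjusted over the list alone (median log2 fold change 0.22, camera adjusted p = 0.0069, adjusted p = 0.80 with an estimated correlation), as for the squalene synthase gene Fdft1 (1.0 ± 0.08). Of 18 glycolysis genes, 2 rose and 11 fell, also adjusted over the list alone (median log2 fold change -0.34, camera adjusted p = 0.019, adjusted p = 0.78 with an estimated correlation), as for the pyruvate kinase gene Pkm (-0.56 ± 0.05). Genes of the unfolded protein and integrated stress responses gave 2 rises and 13 falls among 21, also adjusted over the list alone (median log2 fold change -0.49, camera adjusted p = 0.0079, adjusted p = 0.69 with an estimated correlation), with Sdf2l1 (-0.95 ± 0.05) as an example. Without RA, 4 of the 21 were higher and 0 lower in TG than in WT, or 11 and 1 adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 0.00029, adjusted p = 0.77 with an estimated correlation). Sdf2l1 was among the higher genes (0.55 ± 0.05). Of 33 cell cycle genes, 2 rose and 6 fell with RA in TG, or 1 and 4 adjusted over the list alone (median log2 fold change -0.22, camera adjusted p = 0.035, adjusted p = 0.90 with an estimated correlation), with Mcm3 (-0.41 ± 0.06) down.

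Gimap3 and Gimap9, which encode GTPases of lymphocyte survival, were lower in TG than in WT without RA. Gimap3 stood at 57.2 ± 5.60 FPKM in WT and 7.33 ± 1.70 in TG without RA (-2.82 ± 0.18), and at 128 ± 13.7 and 184 ± 23.8 with RA. Gimap9 stood at 52.4 ± 3.53 and 8.09 ± 1.05 FPKM without RA (-2.56 ± 0.12) and at 92.1 ± 7.13 and 99.2 ± 9.30 with RA, and the RA effects of both differed between TG and WT by 3.34 ± 0.26 and 2.66 ± 0.17. Values within this family of related sequences are uncertain. Interferon response genes were higher in TG than in WT without RA in 3 of 14 (4 higher and 1 lower adjusted over the list alone, median log2 fold change 0.13, camera adjusted p = 0.013, adjusted p = 0.77 with an estimated correlation), as for Cxcl10 (1.40 ± 0.13). With RA they were higher in 5 of 14 (6 and 1 adjusted over the list alone, median log2 fold change 0.26, camera adjusted p = 0.0031, adjusted p = 0.61 with an estimated correlation). Ifit1 (1.45 ± 0.11) and Usp18 (1.42 ± 0.17) were examples.

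In WT, genes of other programmes moved with RA too. The osteoclast factor gene Tnfsf11 rose by 2.12 ± 0.16 and the chemokine receptor gene Cxcr5 by 1.03 ± 0.15, whereas the chromatin organiser gene Satb1 (-1.23 ± 0.11), the selectin ligand enzyme gene Fut7 (-1.46 ± 0.15) and the chemokine receptor gene Ccr4 (-0.60 ± 0.09) fell. Their lists did not pass camera: 25 cytokine genes held 3 rises and 5 falls, 13 follicular helper genes 3 and 2, 23 naive-state genes 2 and 2, and 15 homing genes 3 and 2. Some markers of other cells rose as well: Nkg7 (1.48 ± 0.37), a call that ended without WT 0 nM replicate 1 (0.91) or WT 10 nM replicate 2 (1.08), Crtam (0.93 ± 0.15), which lost it without WT 0 nM replicate 2 (0.88), and Epcam (0.92 ± 0.18), which lost it without WT 0 nM replicate 2 (0.65) or WT 10 nM replicate 1 (0.94) or 2 (0.90). Of 10 tested genes of stress and heat shock, 1 rose and 3 fell, or 2 and 5 adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.11, adjusted p = 0.40 with an estimated correlation), and each of these 4 calls ended without 1 or more single libraries. The interferon list in WT had a median of 0.19 and a mean of -0.03, opposite in sign.

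A hypothesis is that RARα holds RA-responsive genes down when RA is absent, so that these lie lower where Rara is higher and higher where the receptor is reduced. Scores were the mean signed log2 level, and genes were picked from comparisons that shared no library with those tested. Over the 17 genes called in RA in KO, the score without RA was -1.22 and -1.32 in the TG libraries against -0.963 and -0.960 in WT. The mean difference was -0.306 and the median over genes -0.186, and 3 of the 17 had the sign of their RA effect. The gene of the 17 that fell with RA in KO, Lgals3, was higher in TG than in WT by 1.88, which lowers the mean score. Lgals3 lies in the chromosome 14 run in which TG also differed from WT. Over the 4662 genes called in RA in TG, it was -0.0466 and -0.0686 under the KO label against -0.150 and -0.168 in WT, a mean difference of 0.102, and 74.5% had the sign of their RA effect. Both values go in the direction of the hypothesis, with 2 libraries per group and no test across animals. The shift under the KO label and the smaller RA effect there rest on the same untreated libraries, so they are not separate support. Line differences other than Rara could give either shift, and Rara was not lower under the KO label.

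Markers of other cells differed between replicate numbers and between groups. The mean FPKM of the dendritic and class II list was 4.70 and 31.1 in replicates 1 and 2 of WT without RA, and 5.16 and 32.8 in WT with RA. It was 5.27 and 14.5 in KO without RA, 5.08 and 15.5 in KO with RA, 5.44 and 8.66 in TG without RA and 6.39 and 8.54 in TG with RA. That of the 10 B-cell markers was 3.05 and 10.8 in WT without RA, 5.76 and 13.5 in WT with RA, 3.15 and 5.48 in KO without RA and 3.80 and 6.83 in KO with RA. In TG it was 3.25 and 3.62 without and 11.2 and 11.1 with RA, a rise found in both libraries and carried mostly by Ighm. Natural killer cell markers did not move together: without RA Klrd1 stood at 47.2 ± 3.98 FPKM in TG and 12.1 ± 1.32 in WT and Nkg7 at 1.02 ± 0.430 and 2.24 ± 1.73, and with RA Klrd1 stood at 4.76 ± 0.691 and 7.20 ± 1.47 and Nkg7 at 32.7 ± 1.34 and 7.71 ± 3.34. Whether T cells or other cells in the cultures held these transcripts was not tested.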
